A study of Mus musculus with 3 samples.

How the data were processed

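The samples are 3 single-cell RNA libraries of colonic lamina propria mononuclear cells from C57BL/6J mice that drank 1.5% DSS for 7 days and water for 3 more, 1 library each for rat IgG, DATK32 and MECA-367, given at 250 µg 3 times a week per the labels. Per the labels' protocols, viable CD45-positive cells were sorted, libraries were made with a 10x 3' v3.1 kit, and all were sequenced on 1 NovaSeq lane. Per the submitters' processing notes and the file headers, the authors used Cell Ranger 6.0.2 with genome build mm10; the annotation, the cell filter and the strand setting are not stated. The deposited matrices hold counts, raw UMI counts per gene and barcode, for 32285 genes.

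The deposited files list 10826, 8445 and 8387 barcodes for rat IgG, DATK32 and MECA-367, with 30359331, 28030376 and 27846540 UMIs and medians of 1932, 2101 and 2054 UMIs per barcode. Barcodes with at least 500 UMIs, 200 genes and at most 10% mitochondrial counts were kept; 31.9%, 30.7% and 29.6% of barcodes were over the mitochondrial limit. Scrublet scores were computed per library with scanpy 1.11.5 at an expected rate of 8%. Its own threshold marked 1 cell, in DATK32, so the caller did not separate doublets from single cells and doublets largely remain; removing the highest scores at 0.8% per 1000 cells (434, 274 and 278 cells) was added as an alternative. The cells analysed numbered 7367, 5851 and 5890, with medians of 1469, 1524 and 1824.5 UMIs.

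Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9, seed 1) gave 26 clusters over the joined libraries, with no batch correction. A cluster took the class whose markers had the highest mean standardised expression, from 21 marker lists fixed before the data were examined. The thresholds were set after the data were seen: a score of at least 0.5, a lead of at least 0.3 over the next class, at least 3 markers found in 5% of cells, and no majority of another class's markers among the 10 leading genes. By these, 19 clusters were named and 7 were not. T cells were clustered again with 20 components into 10 sub-clusters and named from subset lists.

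Shares are given with exact (Clopper-Pearson) 95% binomial intervals. A share is called higher or lower when both intervals are apart and the ratio is at least 1.5 either way. For expression, raw counts were summed per library and class and given as CPM of the class total with exact Poisson 95% intervals; log2 ratios add 1 count to each count. Only classes with at least 100 cells in each library were used, which leaves out B cells (94 in DATK32). A gene is measured in a class with at least 50 counts over the 3 libraries, and counts as higher or lower at a fold of 1.5 with intervals apart. For 20 gene lists fixed beforehand, the median log2 ratio over measured members (at least 5) was placed among 10000 random lists of the same size drawn from 20 expression bins. With 1 library per group, no p-value was computed and cells were not treated as replicates. Comparisons were DATK32 against rat IgG, MECA-367 against rat IgG, and DATK32 against MECA-367; the first pair share a control.

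Named genes follow a rule fixed before the data were examined. In T cells, neutrophils, and monocytes with macrophages, these are the 3 highest and 3 lowest log2 ratios against rat IgG, and for DATK32 against MECA-367 in T cells and in monocytes with macrophages. Eligible genes had at least 100 counts over both libraries, a count in at least 10% of cells and at least 0.5 times the gene's highest class CPM in the higher library. Mitochondrial, ribosomal, haemoglobin, receptor segment and clone-named genes were left out. Not every gene that the rule picks is given in the text. Members of the lists may also be named; the examples among them, and Vcam1, Icam1 and Madcam1, were picked after their values were seen.

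The ratio steps were tested on simulated data, with counts drawn at the real class totals and known folds put in. In T cells, a simulated log2 fold of 1.0 came back as a median of 0.98 in DATK32 against rat IgG, 0.98 in MECA-367 against rat IgG and 0.98 between the antibodies, and 62.7%, 53.7% and 67.2% of such genes passed the size and interval rule. In neutrophils the share was 44.8%, 58.2% and 44.8%, and in monocytes with macrophages 58.2%, 67.2% and 64.2%. Of genes simulated without a difference, 0.24% to 0.69% passed it in these classes. These figures cover counting error only. They hold no variation between animals and no uneven spread of counts between cells, so false passes in the real data can be more frequent.

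Alternatives changed 1 choice at a time, except that the UMI and gene minimums moved together, the use of every deposited barcode also lifted the mitochondrial limit, and thinning to 1000 UMIs also left out cells under 1000 UMIs. The thinned share of T cells with a leading gene also replaced the sub-clusters. Of T cells, 197 of 589 in rat IgG, 308 of 659 in DATK32 and 551 of 783 in MECA-367 were deep enough to be thinned. They covered cell filters, doublet handling, cluster resolution, variable genes, components, seed, clustering of each library alone, classes picked per cell by markers, thinning to 1000 UMIs, denominators, edgeR 4.0.16 TMM factors (R 4.3.3), gene filters, the added count, and per-cell means. Chosen after seeing the data were the immune denominator, removal of the highest Scrublet scores, variable genes without listed genes and neutrophil markers, cells with over 0.5% epithelial marker UMIs left out, and totals over genes led by the class. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.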

Results

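Colonic lamina propria cells of mice with dextran sulfate sodium (DSS) colitis were profiled in 3 single-cell libraries, 1 from mice given control rat IgG and 1 from each of the antibodies DATK32 and MECA-367. The sample labels call DATK32 the surrogate of ontamalimab and MECA-367 the surrogate of vedolizumab. From general knowledge the clones bind the other way round: DATK32 recognises the integrin alpha4beta7, the target of vedolizumab, and MECA-367 recognises MAdCAM-1, the vessel ligand of that integrin and the target of ontamalimab. Groups are therefore named by clone here, and no drug name is attached to a result. Each group is 1 library, the number of animals behind it is not stated, and so every difference below has no replicate check. Brackets hold exact 95% intervals that cover counting error only.

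The kept cells fell into T cells, NK cells with ILC1, ILC2, B cells, plasma cells, neutrophils, monocytes with macrophages, mast cells or basophils, and 3 non-immune classes. No cluster took a dendritic cell name. The single cluster of monocytes with macrophages scored next highest for a conventional dendritic cell list (0.71 against 1.71), so dendritic cells may lie in it. Epithelial cells (26.9%, 26.6% and 15.1% of the rat IgG, DATK32 and MECA-367 libraries), stromal cells (20.8%, 17.8% and 23.9%) and endothelial cells (1.45%, 1.74% and 1.75%) were present although the labels describe a sort for CD45. Immune classes made up 38.5%, 36.5% and 48.6% of kept cells. Clusters left without a class name, whose thresholds were set after the data were seen, held 12.4%, 17.4% and 10.7%. The stromal class was led by a different cluster in MECA-367 (marked by Adamdec1 and Ccl11) than in rat IgG and DATK32 (marked by Lum and Mgp). Depth differed too: the median T cell carried 763 UMIs in rat IgG, 957 in DATK32 and 1265 in MECA-367, and the median neutrophil 865.5, 1136.5 and 2463.5. The median NK cell or ILC1 carried 735.5, 995 and 1178. The lowest counts among deposited barcodes were 500, 500 and 502 UMIs, so shallower cells are missing under every setting. A loss of shallow rat IgG cells is therefore not set apart from the lower shares of these classes in that library.

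**Figure D1:**
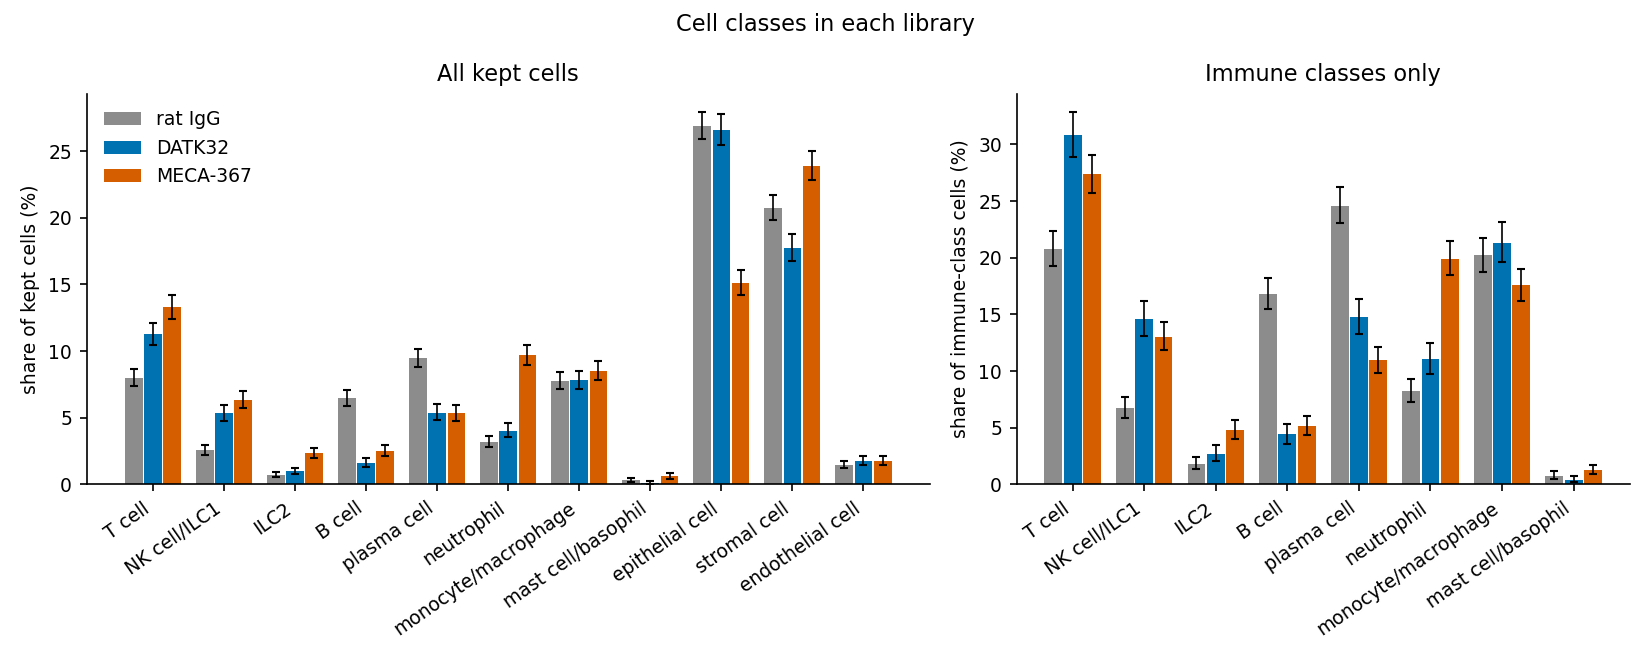
Share of each cell class in each library, among all kept cells (left) and among cells of immune classes (right). Bars are the share in 1 library and whiskers the exact 95% binomial interval, which covers counting error only.

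B cells and plasma cells were scarcer in the DATK32 library than in rat IgG, and NK cells with ILC1 were more frequent. B cells, which in the colon gather mainly in lymphoid follicles, made up 1.61% [1.30 to 1.96] of kept cells against 6.46% [5.91 to 7.05], a log2 ratio of -2.01. Plasma cells, the antibody-secreting stage of the lineage, made up 5.38% [4.82 to 5.99] against 9.46% [8.80 to 10.2] (-0.81). NK cells with ILC1 stood at 5.33% [4.77 to 5.94] against 2.58% [2.23 to 2.97] (1.05, and up to 2.42 with at least 1000 UMIs and 500 genes per cell). Those minimums drop shallow cells, which were more common in rat IgG, so 2.42 is not read as a larger difference. T cells were at 11.3% [10.5 to 12.1] against 7.995% [7.39 to 8.64], a log2 ratio of 0.49 that stays under the 1.5-fold rule, though 3 of 19 other settings put it past. At resolution 0.5 (0.72), NK cells with ILC1 had no value, as no cluster took the name. With each library on its own (1.84), no rat IgG cluster took that name, while clusters of DATK32 and MECA-367 did. The cause of the 1.84 was not tested. Thinning (0.76) drops shallow cells. Neutrophils (4.03% against 3.18%), monocytes with macrophages (7.79% against 7.78%) and ILC2 (0.974% against 0.706%) also stayed under the rule.

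Within the T cells of DATK32, the naive or central memory subset, which carries the lymph node homing genes, was smaller than in rat IgG: 17.8% [14.9 to 20.9] against 27.8% [24.3 to 31.7] of T cells, a log2 ratio of -0.65. That difference is no longer called at a finer sub-clustering (-0.59) or when the single cell marked as a doublet is kept (-0.57). The regulatory sub-cluster was larger, 14.9% [12.2 to 17.8] against 8.49% [6.37 to 11.04] (0.81), but the call was kept in only 1 of 4 alternatives (-0.16 to 0.84). Its direction also turns with the measure. Only 308 of 659 DATK32 and 197 of 589 rat IgG T cells held at least 1000 UMIs; of these, thinned to 1000, 9.09% and 10.2% had a UMI of Foxp3, the lineage factor of regulatory cells (-0.16). Over all T cells without thinning the shares were 7.89% and 6.79%. In stromal cells, which should lack Foxp3, the thinned shares were 0.410% and 0.386%; median depth before thinning was 957 and 763 UMIs in T cells and 1302 and 1012 in stromal cells. The sub-clusters named Th17 (8.80% against 6.96%) and CD8 (3.34% against 3.23%) lay under the rule by share. The one named Th17 scored next highest for the gamma-delta list (0.66 against 1.38). Its leading genes include Cd163l1 and Trdv4 of that list, so it need not hold Th17 cells alone. Cd8a was counted in 11.2% [8.92 to 13.9] of DATK32 against 6.45% [4.61 to 8.75] of rat IgG T cells without thinning, past the rule, and in 8.44% against 7.11% of the thinned cells, under it. In stromal cells those shares were 0.385% against 0.262% without thinning and 0.274% against 0.257% with it. Sub-clusters without a subset name held 53.5% of rat IgG, 55.2% of DATK32 and 61.7% of MECA-367 T cells. Among their leading genes were epithelial genes such as Krt8 and Cldn7 in 1 sub-cluster (46, 44 and 40 cells). Another was led by MHC class II genes such as H2-Ab1 and Cd74 (19, 9 and 11 cells). Both stay in the T cell shares and summed counts.

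**Figure D2:**
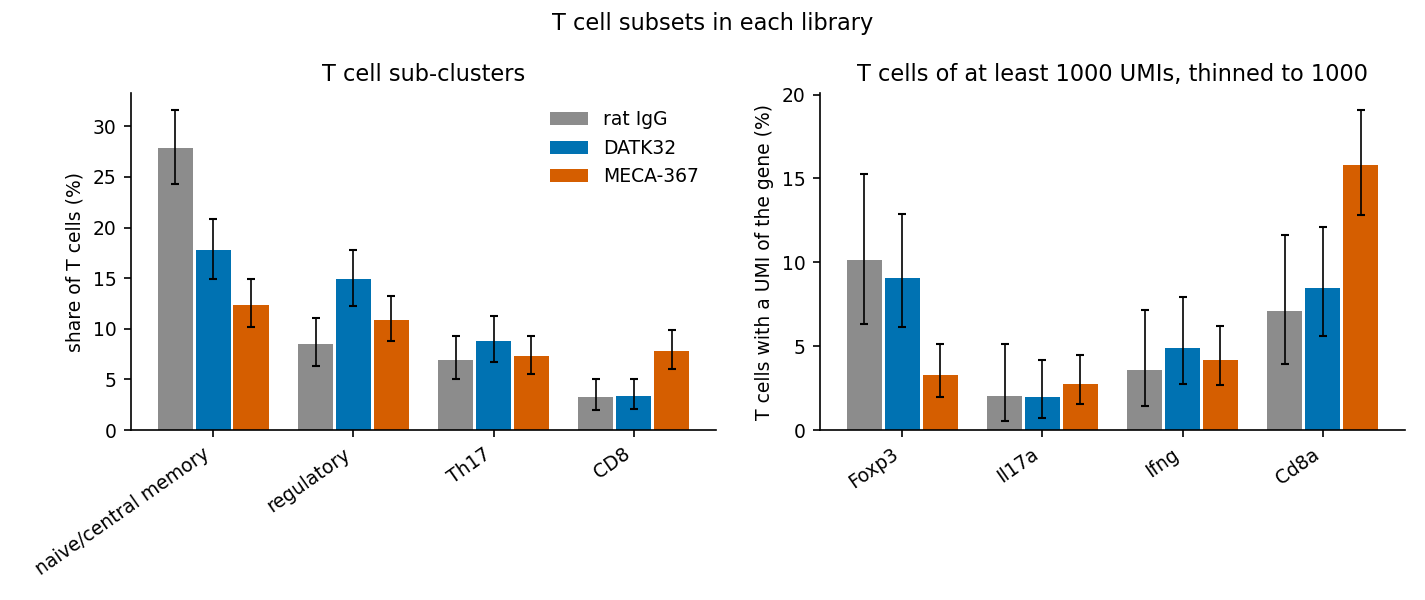
T cell subsets by sub-cluster (left) and T cells with a UMI of a subset's leading gene among those of at least 1000 UMIs, thinned to 1000 (right), in each library. Whiskers are exact 95% binomial intervals covering counting error only.

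T cell expression in DATK32 was lower than in rat IgG for genes of naive lymphocytes and higher for granzyme B. The naive lymphocyte list had a median log2 ratio of -0.48 over 8 measured members. That median sits at percentile 0.01 of 10000 random lists matched on expression, which describes these libraries and does not test the treatment. Of the members, 3 were lower by the size and interval rule and 5 lay between; the lower ones include Ccr7, a receptor for lymph node chemokines (-0.82), and S1pr1, the egress receptor (-1.19). The cytotoxic list had a median of 0.09, with Gzmb (0.87) and the activating receptor gene Klrk1 (1.06) higher and 7 members between. Immunoglobulin constant genes, which T cells should not transcribe, had a median of 1.08 (percentile 100, 3 of 5 members higher and 1 lower), and -0.21 as a mean over cells, -0.54 with a minimum of 10 counts and -0.64 with classes picked by markers. The homing and egress list had a median of -0.12 (percentile 28.68), with 1 member higher, 3 lower and 15 between. The higher one was Ccr2, a receptor for monocyte-attracting chemokines (0.76), and the lower ones include Ccr7 and S1pr1. The genes with the highest ratios were Cops9, of the COP9 signalosome (173.0 against 82.9 CPM, 1.04), Tmem256 (107.9 against 54.7 CPM, 0.95) and Gzmb (488.8 against 266.9 CPM). The lowest were Tsix (103.4 against 195.6 CPM, -0.92), the zinc finger gene Zfp148 (60.7 against 111.1 CPM, -0.87) and Cnot1, scaffold of the CCR4-NOT complex (102.3 against 180.7 CPM, -0.82). Tsix overlaps Xist on the other strand and the counting strand is not stated, so which RNA its counts come from is uncertain.

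Neutrophils of DATK32 carried more RNA of interferon-stimulated genes than those of rat IgG. The list had a median log2 ratio of 1.08 (percentile 100), with 21 of 32 measured members higher and 11 between. Isg15, a ubiquitin-like modifier, was at 829.4 against 284.0 CPM (1.54), the antiviral gene Rsad2 at 423.3 against 152.7 CPM (1.46), and Ifi204, a DNA sensor of the interferon-inducible family, at 286.0 against 103.3 CPM (1.45). The antimicrobial and alarmin list had a median of 0.57, with 7 of 17 members higher, among them S100a8 (0.78), Nos2 (1.52) and Saa3 (1.15). Rat IgG neutrophils held more epithelial RNA: 24.4% of them had over 0.5% epithelial marker UMIs against 13.6% in DATK32, and leaving such cells out lowered the interferon median to 0.84. Monocyte recruitment genes, 10 of them markers of monocytes, were higher in the same neutrophils (0.83, percentile 100, 5 of 12 members higher), and at 0.27 as a mean over cells. The lowest genes were Scd2 (82.0 against 260.3 CPM, -1.65), Phb2 (66.7 against 167.8 CPM, -1.31) and Mlec (72.5 against 165.6 CPM, -1.17). Without those cells Scd2 (0.48) and Phb2 (0.25) turned direction, so their lower values rest on epithelial RNA in the control. Scaling by TMM moved the median over all genes by 0.14 in this comparison.

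Monocytes and macrophages of DATK32 were higher than those of rat IgG in listed monocyte recruitment genes and lower in listed resident macrophage genes. The recruitment list had a median of 0.55 (percentile 100), with 6 of 13 members higher and 7 between: the chitinase-like gene Chil3 was at 783.1 against 302.6 CPM (1.37), F13a1, the coagulation factor XIII subunit, at 178.3 against 89.0 CPM (0.99), and Ly6c2, the inflammatory monocyte marker, at 0.66. The resident macrophage list had a median of -0.52 (percentile 0), with 4 of 11 members lower: the complement genes C1qa (-0.81) and C1qc (-0.75), Apoe (-0.68) and Selenop (-0.59). The MHC class II list had a median of -0.47 (percentile 0), with H2-Aa at -0.47, Cd74 at -0.48 and H2-DMb2 past the rule at -1.37. H2-DMb2 also leads the B cell cluster, and immunoglobulin genes, which these cells should not transcribe, were lower as well (-1.26, 7 of 7 members), so RNA from B-lineage cells is not set apart from this list. Nor is a smaller part of dendritic cells within the class, for this list or for Itgax below. The interferon list (0.36, 6 of 30 higher, including Irf7 at 0.68) and the antimicrobial list (0.27, 4 of 14 higher, including the neutrophil marker S100a8 at 1.78) were shifted less. Bcl2a1d, a survival gene of the Bcl2 family, was also among the highest (237.4 against 112.7 CPM, 1.07). The lowest were the heat-shock gene Hsph1 (62.3 against 131.7 CPM, -1.07), Tsix (50.5 against 103.2 CPM, -1.02) and Itgax, which encodes CD11c (49.4 against 89.0 CPM, -0.84). Of the recruitment list, 10 genes are also markers that name the class.

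In the MECA-367 library, neutrophils, NK cells with ILC1, ILC2 and T cells were more frequent than in rat IgG, while B, plasma and epithelial cells were scarcer. Neutrophils made up 9.68% [8.93 to 10.5] of kept cells against 3.18% [2.79 to 3.60] (1.61, and 2.89 with at least 1000 UMIs and 500 genes per cell), and 19.9% against 8.26% of immune cells (1.27). NK cells with ILC1 stood at 6.33% [5.72 to 6.99] against 2.58% [2.23 to 2.97] (1.30, and 2.86 with those minimums), and ILC2, which make type 2 cytokines, at 2.33% [1.96 to 2.74] against 0.706% [0.528 to 0.925] (1.72, or 0.73 with classes picked by markers). The UMI and gene minimums drop shallow cells, which were more common in rat IgG. T cells were at 13.3% [12.4 to 14.2] against 7.995% [7.39 to 8.64] (0.73), but among immune cells at 27.4% against 20.8% (0.40), under the rule. Their ratio was also under it with 15 components (0.52), a 5% mitochondrial limit (0.47) and without listed genes and neutrophil markers (0.18). With each library on its own it was 2.09. B cells were at 2.496% [2.11 to 2.93] against 6.46% [5.91 to 7.05] (-1.37) and plasma cells at 5.31% [4.76 to 5.92] against 9.46% [8.80 to 10.2] (-0.83). Epithelial cells were at 15.1% against 26.9% (-0.83), which raises every other share among kept cells; that ratio leaves the rule at a mitochondrial limit of 5% (-0.42), with each library clustered on its own (-0.43) and at a coarser resolution (-0.50).

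T cells of MECA-367 held a smaller naive or central memory subset, a larger sub-cluster named CD8 and more cells with Cd8a than those of rat IgG. The naive or central memory subset was 12.4% [10.2 to 14.9] against 27.8% [24.3 to 31.7] of T cells (-1.17). The CD8 subset, a sub-cluster led by Gzma, Ccl5 and Ccl4 that also carries the gamma-delta gene Trdc, was 7.79% [6.01 to 9.90] against 3.23% [1.95 to 4.99] (1.27). Its 10 leading genes include neither Cd8a nor Cd8b1, and Cd8b1 is among those of the naive or central memory subset. The name thus covers cytotoxic T cells that need not be CD8 cells. Only 551 of 783 MECA-367 and 197 of 589 rat IgG T cells held at least 1000 UMIs; of these, thinned to 1000, 15.8% [12.8 to 19.1] and 7.11% [3.94 to 11.6] had a UMI of Cd8a. Over all T cells without thinning the shares were 19.3% and 6.45%. In stromal cells the thinned shares were 0.161% and 0.257%, with median depths before thinning of 1899 and 1012 UMIs there and 1265 and 763 in T cells. The regulatory sub-cluster (10.9% against 8.49%) and the one named Th17, which also carries gamma-delta genes (7.28% against 6.96%), lay under the rule. For regulatory cells the measures conflict. Among the thinned cells the Foxp3 share was 3.27% [1.95 to 5.11] against 10.2% [6.31 to 15.2], lower past the rule. Over all T cells without thinning it was 4.598% against 6.79%, with overlapping intervals.

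T cell expression in MECA-367 was lower than in rat IgG for naive and immediate-early genes and higher for cytotoxic genes. The naive list had a median of -0.78 (percentile 0), with 5 of 8 members lower, among them Ccr7 (69.2 against 202.2 CPM, -1.54), S1pr1 (-1.45), the transcription factor gene Lef1 (-0.82) and Klf2 (-0.73). Genes of other cell types also differed in these T cells. The sub-cluster led by MHC class II genes, part of this class, held 11 MECA-367 and 19 rat IgG cells. The neutrophil markers S100a8 (41.4 against 11.6 CPM, 1.67) and S100a9 (56.3 against 19.9 CPM, 1.40) were higher. Lower lists were immunoglobulin constant genes at -1.09 (percentile 0, 4 of 5 members lower), MHC class II genes at -1.33 (percentile 0, 3 of 6 lower) and monocyte recruitment genes at -0.49 (percentile 0.27, 3 of 7 lower and Plac8 higher at 1.24). The cytotoxic list had a median of 0.58 (percentile 99.97), with 4 of 9 higher and 5 between: the granzyme genes Gzma (1.48) and Gzmb (1.01), Klrk1 (1.22) and the chemokine gene Ccl5 (0.60). The immediate-early and dissociation list had a median of -0.59 (percentile 0), with 9 of 19 lower, among them Egr1 (-1.37), Fos (-0.60) and Hspa1a (-0.59); such genes also respond to tissue handling. The homing and egress list had a median of -0.31, and Gpr183, an oxysterol receptor gene, was among its 5 lower members (-0.78). Among the highest genes were Hist1h2ap (264.6 against 74.6 CPM, 1.80) and the CD200 receptor family gene Cd200r4 (79.9 against 24.9 CPM, 1.60). The lowest besides Ccr7 were Nmt1, a protein N-myristoyltransferase gene (49.9 against 160.8 CPM, -1.68), and Tsix (62.0 against 195.6 CPM, -1.65). Hist1h2ap has near-identical copies elsewhere in the genome, so the assignment of its reads is uncertain.

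Neutrophils of MECA-367 were richer than those of rat IgG in antimicrobial and alarmin genes and in interferon-stimulated genes. Ltf, which encodes the secondary granule protein lactoferrin, had 1094 counts against 4 (548.5 against 8.61 CPM, 5.67), a ratio of 63.7 [24.8 to 234.0]; it was 1.03 when neutrophils were picked by markers without clustering. Camp, the cathelicidin gene, had 867 counts against 5 (434.7 against 10.8 CPM, 5.08), and 3.95 without cells that carry epithelial RNA. Scrg1 had 100 counts against 1 (3.56), a ratio of 23.3 [4.09 to 930.0]. The antimicrobial and alarmin list had a median of 1.12 (percentile 100), with 16 of 17 members higher, including Ngp (2.66), Lcn2 (1.80) and S100a8 (1.12), and a median of 0.37 without cells over 0.5% epithelial marker UMIs (10.9% of MECA-367 and 24.4% of rat IgG neutrophils). The interferon-stimulated list had a median of 0.98 (percentile 100), with 21 of 32 members higher, such as Isg15 (1.24) and Igtp (1.40), and 0.30 without those cells. Monocyte recruitment genes were higher in the same neutrophils (0.43, percentile 99.6, 4 of 12 members higher), but at -0.13 without those cells and -0.47 as a mean over cells. The immediate-early list was lower (-0.83), with 12 of 19 members lower, including Fos (-1.11) and Hspa1b (-1.58). The lowest genes, Scd2 (39.1 against 260.3 CPM, -2.73), the UDP-glucose dehydrogenase gene Ugdh (28.6 against 133.4 CPM, -2.22) and the sulfotransferase gene Sult1a1 (33.1 against 135.5 CPM, -2.04), came closer to the control once mixed cells were set aside: without cells carrying epithelial RNA Scd2 was at -1.64 and Ugdh at -0.98. Scaling by TMM moved the median over all genes by 0.33. S100a8, Lcn2, Ngp, Camp and Ltf are also markers that name the class.

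**Figure D3:**
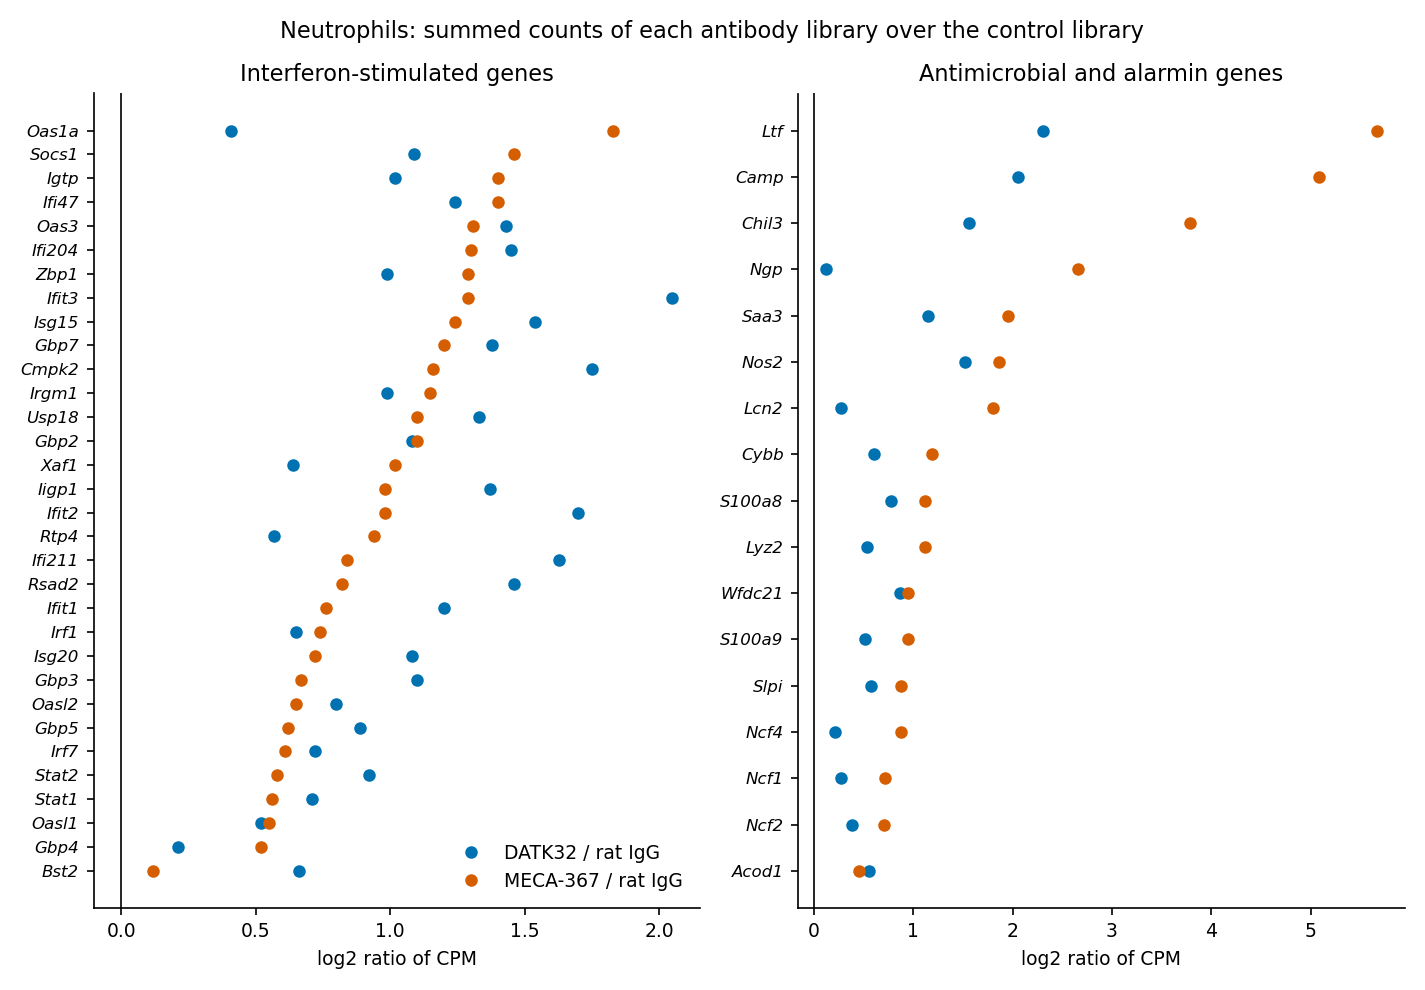
Log2 ratio of CPM in neutrophils of each antibody library over the rat IgG library, for measured members of the interferon-stimulated list (left) and the antimicrobial and alarmin list (right). Both ratios share 1 control library whose neutrophils hold more epithelial RNA.

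Monocytes and macrophages of MECA-367 were higher than those of rat IgG in antimicrobial and alarmin genes. Chil3 was at 1119.9 against 302.6 CPM (1.88), Ms4a8a at 174.6 against 47.5 CPM (1.85), and Saa3, a serum amyloid gene of the antimicrobial list, at 8499.6 against 2731.3 CPM (1.64). The antimicrobial list had a median of 0.65 (percentile 100), with 7 of 14 members higher, among them Nos2 (1.35) and Lcn2 (1.05). Of the listed genes 8 are neutrophil markers, which moved both ways here (Wfdc21 at 1.77, S100a8 at 0.88 and S100a9 at -0.33), and S100a8 and S100a9 were higher in T cells of this library too, so RNA from neutrophils is not set apart from this list. The recruitment list had a median of 0.41 (percentile 99.89), with 5 of 13 higher, including Plac8 (1.06); as a mean over cells it was 0.20 and with classes picked by markers 0.16, both inside the central 95% of random lists. The glycolysis and hypoxia list had a median of 0.42, with 7 of 18 higher, such as Eno1 (0.99) and Bnip3 (1.13), and Hk2 lower (-0.61). The interferon list had a median of 0.20 (percentile 99.8), with 3 of 30 members higher, among them Gbp4 (0.93), and 2 lower, among them Ifit1 (-1.19). The MHC class II list was at -0.31 (percentile 1.36) and the resident macrophage list at -0.18 (percentile 24.7), where C1qb was higher (0.72) and Mrc1, the mannose receptor gene (-1.62), and Cx3cr1 (-1.56) were lower. Dendritic cells within the class are not set apart from the MHC class II value. The lowest genes were Polr2l, a shared RNA polymerase subunit gene (25.3 against 104.4 CPM, -2.02), Tsix (35.7 against 103.2 CPM, -1.52) and the RNA helicase gene Ddx21 (57.8 against 156.6 CPM, -1.43). Scaling by TMM moved the median over all genes by 0.13.

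Set directly against MECA-367, the DATK32 library had fewer neutrophils, ILC2, B cells and mast cells or basophils, and more epithelial cells. Neutrophils were at 4.03% [3.54 to 4.57] against 9.68% [8.93 to 10.5] (-1.26), ILC2 at 0.974% [0.739 to 1.26] against 2.33% [1.96 to 2.74] (-1.26, or -0.30 with classes picked by markers), mast cells or basophils at 0.137% [0.059 to 0.269] against 0.611% [0.428 to 0.845] (-2.16) from 8 and 36 cells, and epithelial cells at 26.6% against 15.1% (0.82, or 0.03 with each library clustered on its own). B cells were at 1.61% against 2.496% (-0.64), but among immune cells at 4.399% against 5.14% (-0.22), under the rule. That call was kept in 13 of 19 alternatives (-0.93 to -0.10). T cells (-0.24), NK cells with ILC1 (-0.25) and plasma cells (0.02) were close. Within T cells the sub-cluster named CD8, led by cytotoxic genes and not by Cd8a or Cd8b1, was smaller in DATK32, 3.34% [2.10 to 5.01] against 7.79% [6.01 to 9.90] (-1.22).

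T cells of DATK32 had less Gzma (-1.23) and more Ccr7 (0.73) RNA than those of MECA-367. The cytotoxic list had a median of -0.29 (percentile 1.65) and the naive list 0.28 (percentile 99.3). Genes of other cell types stood further apart in these T cells: immunoglobulin constant genes at 2.47, or 0.17 with a minimum of 10 counts, MHC class II genes at 1.33 and monocyte recruitment genes at 0.85, each median at percentile 100. The neutrophil markers S100a8 (-1.23) and S100a9 (-1.50) were lower. Proliferation genes had a median of -0.34 (percentile 0.01), with Rrm2 (-1.40) and Cdk1 (-0.97) lower and 21 of 23 members between. The highest genes were Atp5k, a subunit gene of ATP synthase (379.8 against 154.8 CPM, 1.29), Nmt1 (118.0 against 49.9 CPM, 1.23) and Pet100, a cytochrome c oxidase assembly factor gene (127.0 against 57.8 CPM, 1.13). The lowest were the fatty acid binding gene Fabp5 (97.8 against 221.8 CPM, -1.17), Ddt (73.0 against 158.3 CPM, -1.10) and Dut, a dUTPase gene of nucleotide metabolism (98.9 against 211.1 CPM, -1.08). As means over cells Fabp5 was at -0.29 and Dut at -0.35, so both depend on how cells are weighted.

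Neutrophils of DATK32 had less antimicrobial RNA than those of MECA-367, while the antimicrobial list of monocytes and macrophages lay inside the central 95% of random lists (-0.14, percentile 5.55, with 2 of 14 members higher and 3 lower). In neutrophils the antimicrobial list had a median of -0.58 (percentile 0), with 8 of 17 members lower, among them Ltf (-3.36), Camp (-3.03), Ngp (-2.54) and Lcn2 (-1.53); without cells that carry epithelial RNA the median was -0.25. The neutrophil interferon list had a median of 0.16, but it exceeded 23 other neutrophil markers (-0.20) by 0.35 [0.18 to 0.50]. Without cells that carry epithelial RNA, its medians against rat IgG were 0.84 in DATK32 and 0.30 in MECA-367. A lack of difference between the antibodies is therefore not read from the 0.16. TMM scaling moved the median over all genes by -0.18. In monocytes and macrophages Saa3 (3258.1 against 8499.6 CPM, -1.38), Ms4a8a (69.8 against 174.6 CPM, -1.31) and the complement gene C1qb (213.8 against 505.7 CPM, -1.24) were the lowest genes. Atp5k (302.9 against 113.0 CPM, 1.42), the translation initiation gene Eif3j1 (126.8 against 51.3 CPM, 1.30) and the kinase gene Prkx (80.6 against 35.1 CPM, 1.19) were the highest. The glycolysis and hypoxia list had a median of -0.38 (percentile 0), with Eno1 (-0.71) and Ero1l (-0.63) lower and Hk2 higher (0.82). The resident macrophage list (-0.24, percentile 0.54) was split, with C1qa (-0.65) and Apoe (-0.61) lower and Mrc1 (1.29) and Pltp (1.43) higher.

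Transcripts of the antibodies' targets were found where general knowledge places them. Madcam1, the gene of the vessel ligand, was counted in endothelial cells at 292.7 CPM [213.5 to 391.6] in rat IgG, 148.6 [96.1 to 219.3] in DATK32 and 62.5 [34.2 to 104.9] in MECA-367. These values come from 12 of 107, 7 of 102 and 3 of 103 endothelial cells, so they rest on few cells, and intervals for counts understate that spread. Vcam1, another ligand of alpha4 integrins, was at 546.3, 558.6 and 223.3 CPM, and Icam1 at 722.0, 730.9 and 665.4 CPM. The Vcam1 values also rest on few cells (30, 24 and 11), with 20 of the 50 counts of MECA-367 in 1 cell. In T cells the integrin gene Itga4 was at 261.9, 175.3 and 193.3 CPM (log2 ratio to rat IgG -0.58 in DATK32 and -0.44 in MECA-367), and its partner Itgb7 at 150.8, 124.7 and 149.0 CPM (-0.28 and -0.03). Antibody bound to a protein on the cell surface would not be seen in these counts.

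**Figure D4:**
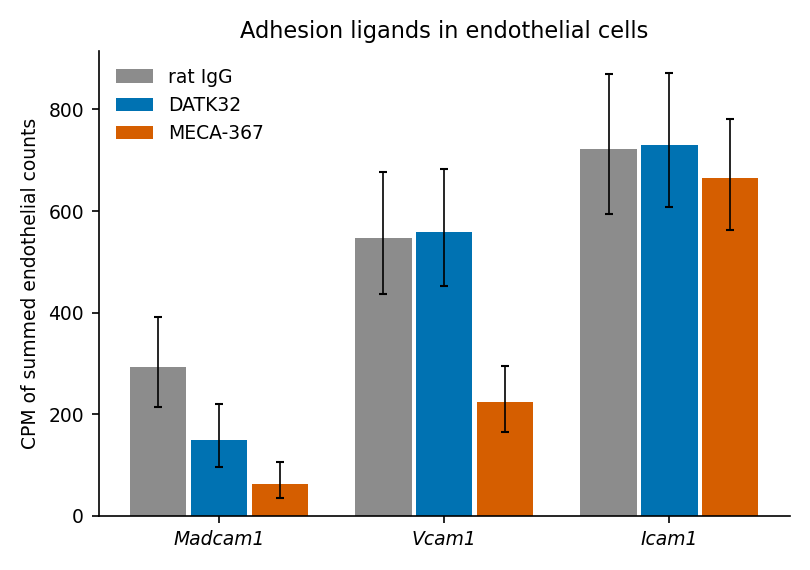
CPM of Madcam1, Vcam1 and Icam1 in the summed endothelial counts of each library. Whiskers are exact 95% Poisson intervals covering counting error only.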

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

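All tests in this part were chosen after the results were seen. A pair of clusters took no class name, so they lie outside every comparison of classes; each held a larger share of DATK32 than of rat IgG, with intervals apart. Cluster 2, led by Etv1, Ano1 and Kit, genes of the pacemaker cells of the gut wall, made up 4.39% of DATK32 [3.88 to 4.95] against 3.38% [2.98 to 3.82] of rat IgG, under the 1.5-fold rule and so not called higher, and 1.73% of MECA-367. Cluster 8, led by the non-coding RNAs Gm42418 and Rmrp and by Lars2, with a median of 858 UMIs, made up 8.14% of DATK32 and 6.67% of MECA-367 against 3.95% of rat IgG. Its best marker score was epithelial (0.44), just short of the naming threshold, so its cells would add to the epithelial share if that threshold were lower.

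B cells were scarcer in both antibody libraries than in the single control library. Named non-immune classes were no larger, at 46.1% of DATK32 and 40.7% of MECA-367 against 49.1% of rat IgG. Clusters without a name held 17.4% and 10.7% against 12.4%, and immune classes 36.5% and 48.6% against 38.5%. The part outside the immune classes was thus slightly larger in DATK32. It does not account for the B cell difference, as among immune cells alone the ratio nearer to 0 was -1.71. Depth and cell filters do not account for it either: among cells of at least 1000 UMIs, thinned to that number and clustered again, the ratio nearer to 0 was -1.50, from 160, 41 and 54 B cells. More follicle tissue in the control library would also bring naive T cells, and the naive or central memory share of T cells was lower in both antibody libraries, by a log2 ratio of -0.65 for the one nearer to 0 (DATK32, no longer called at a finer sub-clustering, -0.59, or with the marked doublet kept, -0.57), so this explanation stays open. An effect of the antibodies on entry of naive lymphocytes stays open too, untested, since 1 library per group cannot part it from the piece of tissue taken.

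Interferon-stimulated genes were higher in neutrophils of both antibody libraries. Epithelial RNA in control neutrophils would lower all neutrophil genes alike; for DATK32 the list exceeded 23 other neutrophil markers by 0.67 [0.47 to 0.84], so dilution is not the whole cause there. For MECA-367 leaving out cells with epithelial RNA took the median from 0.98 to 0.30, in line with dilution as most of the difference, though the list still exceeded those markers by 0.28 [0.09 to 0.44]. The rise does not need shallow control neutrophils, as cells with at least 1000 UMIs gave medians of 1.31 or more. Deep cells weigh most in summed counts in any case. As means over cells, which weight shallow cells alike, the medians were lower, 0.92 in DATK32 and 0.54 in MECA-367. For DATK32 the list was also raised in T cells (0.23, percentile 99.93) and in monocytes with macrophages (0.36, percentile 100). A shift of the whole control library thus stays open as part of the rise there. It is not the whole cause, as the neutrophil median without cells with epithelial RNA was 0.84. For MECA-367 the list stood at 0.10 (percentile 92.63) and 0.20 (percentile 99.8) in those classes. Such a shift is not set apart from the 0.30 left in its neutrophils. Monocyte RNA does not account for the rise in DATK32, which would need a median share of 0.75 [0.64 to 0.92]. The 40 monocyte and macrophage markers stood at 0.16 [0.14 to 0.20] of their level in monocytes with macrophages. An effect of DATK32 treatment stays a hypothesis, found and tested on the same data.

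Epithelial, stromal and endothelial cells made up 49.1%, 46.1% and 40.7% of the libraries, although the labels describe sorting for CD45. Free RNA in empty droplets does not account for most epithelial cells, since each epithelial cluster but 1 held at least 2.33 times the median UMIs of T cells. For the epithelial cluster led by histone genes (203, 354 and 259 cells, at 1.07 times or more), depth does not decide and free RNA stays open. Depth does not decide for stromal and endothelial cells either (1.04 times or more). Their barcodes held a median of 0.0% epithelial marker UMIs in every library, against 2.23%, 1.95% and 1.69% in epithelial cells. Free RNA drawn from all cells of a library would carry such markers, so these values argue against it for most of these barcodes. The make-up of free RNA was not measured. Attachment to a CD45-positive cell does not account for most non-immune cells: the share of barcodes with Ptprc, the gene of CD45, was at most 0.052 of that in T cells for epithelial cells and 0.177 for stromal or endothelial cells. A sort that let CD45-negative cells through, or input that was not sorted, stays open, untested.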

How the results depend on the processing

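Values in this part are log2 ratios of shares or median log2 ratios of lists; where a value left its counting interval or turned direction, the cause was not tested unless stated. Which list medians lead was chosen after the values were seen, as were the alternatives that use immune cells, the highest Scrublet scores, variable genes without listed genes and neutrophil markers, epithelial RNA, or genes led by the class. All 19 alternatives kept the calls of B cells (-2.17 to -1.70 in DATK32, -1.75 to -1.24 in MECA-367, both against rat IgG) and plasma cells (-0.89 to -0.66 and -1.17 to -0.71). All 18 kept that of neutrophils in MECA-367 (1.04 to 2.89), and 17 of 17 those of NK cells with ILC1. Neutrophils in DATK32 stayed under the rule in all 18 (0.08 to 0.63), while T cells in MECA-367 passed it in 15 of 19. The subset named CD8 kept its calls in MECA-367 (1.11 to 1.20) and between the antibodies (-1.13 to -0.90) in all 4, and mast cells or basophils theirs (-2.53 to -1.39) in 11. In total 245 of 294 values of the leading class shares, 16 of 18 of the subset shares and 84 of 115 of the leading list medians stayed within counting error. Of 150 list medians, 75 lay outside the central 95% of random lists, and 16 of these turned direction in at least 1 alternative. Outside the leading results, 37 class share, 5 subset share, 292 list and 20 named-gene values moved; of these 13, 3 and 49 of the first groups changed sign and none of the named genes did, all from ratios or medians that were not called.

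For shares, ratios are against rat IgG unless stated. At least 1000 UMIs and 500 genes gave NK cells with ILC1 2.42 (DATK32) and 2.86 (MECA-367), and in MECA-367 T cells 1.01, epithelial cells -1.41 and neutrophils 2.89; DATK32 against MECA-367 gave neutrophils -2.25, epithelial cells 1.13 and B cells -0.10, which ended that call. Thinning to 1000 UMIs gave NK cells with ILC1 1.87 and 2.25, T cells 0.76 and 1.47, and in MECA-367 neutrophils 2.26 and epithelial cells -1.50; between the antibodies, neutrophils -1.71 and epithelial cells 1.22. Both settings drop shallow cells, which were more common in rat IgG. A 5% mitochondrial limit gave in MECA-367 B cells -1.75, T cells 0.47 and epithelial cells -0.42. Every deposited barcode gave neutrophils 1.27 in MECA-367 and epithelial cells 0.63 between the antibodies. With 15 components NK cells with ILC1 were at 1.61 and 2.20, and in MECA-367 T cells at 0.52 and epithelial cells at -0.68. Resolution 0.5 gave T cells 0.72 and 1.03 and epithelial cells -0.50 in MECA-367. Epithelial cells in MECA-367 were at -1.12 with resolution 2.0, -1.12 with more variable genes, -1.09 with seed 2, -1.13 with doublets kept and -0.67 with receptor and cycle genes out. Each library on its own gave T cells 1.84 and 2.09, in MECA-367 neutrophils 1.04 and epithelial cells -0.43, and between the antibodies neutrophils -0.96 and epithelial cells 0.03. Without listed genes and neutrophil markers T cells were at 0.25 and 0.18, and epithelial cells at -1.18 in MECA-367 and 0.97 between the antibodies. Picking classes by markers gave ILC2 0.73 in MECA-367 and -0.30 between the antibodies. Among immune cells MECA-367 had T cells at 0.40, neutrophils at 1.27 and plasma cells at -1.17, and neutrophils between the antibodies were at -0.85. For subsets, the thinned leading-gene share turned regulatory cells in DATK32 to -0.16 and put those in MECA-367, not called at 0.35, at -1.64, and a finer sub-clustering put naive or central memory cells in MECA-367 at -1.67. The leading-gene share was not used here for naive or central memory cells.

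For leading lists, TMM factors gave in MECA-367 neutrophils interferon 1.30 and antimicrobial 1.44, between the antibodies antimicrobial -0.76, and monocyte recruitment in MECA-367 0.54. Per-cell means gave neutrophil interferon 0.92 (DATK32) and 0.54 (MECA-367), antimicrobial 0.64 (MECA-367) and -0.43 (between), and recruitment 0.20 in MECA-367, which ended the call. Cells with at least 1000 UMIs gave interferon 1.31 and 1.33, antimicrobial 1.81, T cell cytotoxic genes 1.02 in MECA-367 and recruitment 0.72 in DATK32. Classes by markers gave interferon 0.78 and 0.60, antimicrobial 0.88, recruitment 0.71 and 0.16 (the latter without a call) and T cell naive genes -0.42 in MECA-367. A minimum of 10 counts put T cell naive genes at -1.14. Without cells over 0.5% epithelial marker UMIs interferon was at 0.84 and 0.30 and antimicrobial at 0.37 and -0.25 (between). Totals over genes led by the class gave interferon 0.69 in MECA-367 and antimicrobial 0.83 and -0.42; members led by the class gave antimicrobial 0.95 and recruitment 0.57 in MECA-367. Removing the highest Scrublet scores gave interferon 1.28 in DATK32.

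These other called values turned direction. Without cells carrying epithelial RNA, in neutrophils: Scd2 0.48 and Phb2 0.25 in DATK32, and in MECA-367 T helper regulators -0.25, chemokines -0.23, homing receptors -0.22, recruitment genes -0.13 and oxidative phosphorylation 0.10. Per-cell means: in neutrophils chemokines -0.34 (DATK32) and -0.15, T helper regulators -0.30, homing receptors -0.11 and recruitment genes -0.47 (MECA-367); in T cells immunoglobulin genes -0.21 in DATK32 and proliferation genes -0.58 in MECA-367; in monocytes with macrophages immunoglobulin genes -1.60 in MECA-367. Classes by markers, all in DATK32: Phb2 0.22, chemokines -0.03 and proliferation genes 0.51 in neutrophils, chemokines -0.26 and immunoglobulin genes -0.64 in T cells, and naive genes 0.01 in monocytes with macrophages. A minimum of 10 counts: T helper regulators -0.13 in MECA-367 neutrophils, immunoglobulin genes -0.54 in DATK32 T cells and -0.32 in MECA-367 monocytes with macrophages. A minimum of 200 counts: T cell interferon genes -0.06 between the antibodies. Highest Scrublet scores removed: chemokines -0.15 in DATK32 neutrophils, immunoglobulin genes -0.64 in MECA-367 monocytes with macrophages and inflammatory cytokines -0.12 in MECA-367 T cells. Cells with at least 1000 UMIs: proliferation genes -0.22 in MECA-367 T cells. Doublets kept, or totals over genes led by the class: T helper regulators -0.06 and -0.01 in MECA-367 neutrophils. Members led by the class: homing receptors -0.14 and immediate-early genes -0.19 in T cells between the antibodies.

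Some alternatives gave no value because no cluster took the name: NK cells with ILC1 at resolution 0.5, and against rat IgG with each library on its own, ILC2 in 6 settings, and mast cells or basophils in 8. Depth limits single genes in small classes: class totals in rat IgG were 153748 UMIs for endothelial cells, 198517 for NK cells with ILC1 and 464839 for neutrophils.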

Other observations

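All tests and values in this part were chosen after the data were seen. Interferon gamma RNA was found in a larger share of NK cells with ILC1 than of T cells. Ifng was found in 33.2% [26.5 to 40.3] of rat IgG, 32.4% [27.2 to 37.9] of DATK32 and 36.2% [31.3 to 41.3] of MECA-367 NK cells with ILC1, at 977.2, 1496.8 and 2046.4 CPM; the cell with most held 22 of 194, 100 of 587 and 201 of 1098 counts. In stromal cells, which should lack it, 0.981%, 0.770% and 1.14% had a count, at median depths of 1012, 1302 and 1899 UMIs against 735.5, 995 and 1178 in NK cells with ILC1 and 763, 957 and 1265 in T cells. In T cells it stood at 53.0, 46.1 and 437.9 CPM; the cell with most held 2 of 32, 5 of 41 and 216 of 614 counts, and 4.58%, 4.55% and 7.02% of T cells had a count. Il22, a cytokine that acts on epithelium, was at 240.4, 637.1 and 378.0 CPM in T cells, from 16, 30 and 37 cells (2.72%, 4.55% and 4.73%), and the cell with most held 37 of 145, 123 of 567 and 88 of 530 counts. In stromal cells 0.916%, 0.577% and 0.426% had a count of it. Il17a was at 59.7, 91.0 and 113.4 CPM in T cells, from 11, 19 and 23 cells (1.87%, 2.88% and 2.94%), with 11 of 36, 22 of 81 and 31 of 159 counts in 1 cell, against 0.196%, 0.096% and 0.498% of stromal cells. Few cells carry these CPM values, so no order of the libraries is read from them.

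Squamous cells and cells with pancreatic enzyme genes were each not detected in 1 library. A cluster of squamous epithelium led by Krt14, Krt5 and Krt6a, as lines the anal canal, held 231 cells of rat IgG (3.14%), 179 of DATK32 (3.06%) and 0 of MECA-367, where the upper limit is 0.063%. A cluster led by the pancreatic enzyme genes Ctrb1 and Prss2 held 33 cells of rat IgG, 0 of DATK32 (upper limit 0.063%) and 2 of MECA-367. Among cells of the colon itself, those with Myh11 and Actg2, genes of smooth muscle, made up 3.11%, 2.63% and 2.97%, with overlapping intervals, and enteroendocrine cells with Chga and Tph1 0.937%, 0.769% and 0.611%. Goblet cells, led by Muc2 and Spink4, made up 10.4%, 9.93% and 4.91%. A cluster of 185 cells with both neutrophil (S100a8) and stromal genes had the highest mean doublet score, 0.255, and was left without a name.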
